A study of Mus musculus with 4 samples.

How the data were processed

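Gene expression was measured in granulocyte/monocyte progenitors (GMP), bone marrow cells purified by flow cytometry, on 4 Affymetrix arrays, 1 wild type and 1 Icsbp-deficient array of each of 2 array types, named 430A and MOE430_2 here. Per the labels and the series' design text, each array carried RNA from a separate preparation of pooled marrow, from at least 10 wild type or at least 8 Icsbp-deficient mice, and the animals were 10 to 16 weeks old. The genotype was read from the sample labels for 3 arrays. The label of the wild type 430A array names GMP of a mixed C57/Bl6 and S129Ola background without a genotype, and it was placed in the wild type group through the design text, which puts the first wild type preparation on the 430A array. A further Icsbp-deficient preparation that the design text describes is not analysed here.

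The deposited values are signal intensity per probe set on a linear scale, with 22690 probe sets on each 430A array and 45101 on each MOE430_2 array. Per the labels' protocols, the Icsbp-deficient 430A sample was labelled with an ENZO kit and both MOE430_2 samples with a one-cycle kit. The kit of the wild type 430A sample is not given in the sources used here, so it is not known whether labelling differed between the genotypes of that type. GCOS is named for the MOE430_2 arrays per the submitters' processing notes, and its version and settings are not given in the sources used here. The 2% trimmed mean of the deposited signals was 500.2 on the wild type 430A array and 167.7 on the Icsbp-deficient 430A array, against 82.08 and 80.62 on the wild type and Icsbp-deficient MOE430_2 arrays. The deposited values were therefore not on a common scale between the genotypes of the 430A type, and the target to which each had been scaled is not given in the sources used here.

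All 22690 probe sets of the 430A array were also on the MOE430_2 array. Of these shared probe sets 64 control probe sets were left out, which left 22626, and each array was scaled to a trimmed mean of 500 over the 22626. An offset of 50 was added, log2 was taken, and the 2 arrays of each type were quantile normalized against each other. Ratios are on this log2(value + offset) scale, which understates the change of genes with low signal. The 9050 probe sets whose mean over the 4 arrays lay under the 40th percentile were not tested, and 13576 were. Of the shared probe sets, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1555 are unnamed here. Symbols were updated through the RefSeq gene table of assembly GRCm38.p6, which matched 20351 probe sets. This table was used for names and for the order of neighbouring genes only. Probe sets with several symbols or none were left out of gene counts. A gene was represented by its tested probe set with the highest mean signal, which gave 7820 genes.

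Each array type gave 1 ratio of Icsbp-deficient over wild type, and the test asked whether the 2 ratios differed from 0 together. It was run with limma 3.58.1 in R 4.3.3 (lmFit with array type as a block, eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Array type was kept as a block because the arrays of 1 type share the array design and, on the MOE430_2 type, the labelling kit. Log2 signals correlated at 0.9798 and 0.9793 between the genotypes of a type, and at 0.9589 and 0.9584 between the types of a genotype. These signals were already quantile normalized within each type and not across types. That can raise the correlation within a type, so the comparison does not itself justify the block. This left 1 residual degree of freedom per gene, to which the moderation across genes added 9.65 prior degrees of freedom. Errors given as ± are the moderated standard errors of the mean of n = 2 ratios. The number of arrays limits the precision, since the spread of a single gene was estimated from 2 ratios and borrowed from other genes.

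The 29 gene lists, the rule for naming genes, the tests and the alternative settings were chosen before the data were examined. The lists hold markers of myeloid stages and of other cell types the sort could hold, myeloid functions, reported IRF8 targets, cell cycle, apoptosis, interferon response, stress response, sex-linked genes and housekeeping complexes. The 27 lists with at least 5 tested members were compared with all other genes by limma's camera with a preset correlation of 0.01 and adjusted together. Camera with an estimated correlation and fry, which tests movement in 1 direction or, as its mixed form, in either direction, were alternatives. Both alternatives take their error from the 1 residual degree of freedom per gene. They could therefore call few lists, and a list that did not pass them is not shown to be unmoved. For each array type alone, a list's median ratio was placed among 10000 random lists of the same size matched on mean signal. The named genes are Irf8; the 15 largest rises and 15 largest falls among called genes that changed at least 2-fold on both array types; in each list the 4 members with the largest change and the members that passed, up to 8; and the 5 largest rises and falls among genes with a symbol over the probe sets carried only by the MOE430_2 array, where Ptgfrn, Ikzf2, Ms4a2, Angpt1 and Ctsh also have other probe sets on the 430A array. The rule also asked for genes with at least 4-fold changes in opposite directions on the array types, of which there were 0. Other genes named were chosen after their values were seen and are the remaining members of small counts, the Mpo group, Csf1r, Kit, H2-Ab1, H2-Oa, late neutrophil markers, neighbours of Irf8 and the genes that open the other observations.

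Alternatives were other normalizations (scaling alone, quantile over all 4 arrays, cyclic loess, values as deposited), other offsets, a floor, other filters, other variance models, the mean of a gene's probe sets, the model without the block, and leaving out arrays. With 2 arrays per genotype, the other ways of dividing the arrays are too few to test the counts against. The steps were tested on simulated data made from the real mean signals and the estimated spread. In 10 simulations with 200 changed probe sets among 13576 tested, the fit called 60.6% of 2-fold changes and 99.3% of 4-fold changes, with 0 calls in the wrong direction. Unchanged probe sets made up 8.92% of the calls, above the nominal level, mostly through 1 simulation. In 10 simulations without changes, the mean was 2.7 calls and the highest 13. At an unadjusted p under 0.05, camera called 20 of 20 lists whose members were all shifted by 1 known amount and 1 of 20 lists that were not. That shift was larger than the median of most lists called in the data, so smaller shifts were not tested. Simulated spreads were drawn from the form of distribution that the moderation assumes. The simulated errors were independent between probe sets, so this does not test camera on lists of genes that vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.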

Results

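Icsbp, also called Irf8, is a transcription factor of the interferon regulatory factor family with known roles in the choice between monocytic and granulocytic development. The study compared GMP, the bone marrow progenitors that give rise to granulocytes and monocytes, from Icsbp-deficient and wild type mice, and the comparison asks which genes differ between them before the cells mature. The data are 4 arrays, with 2 Icsbp-deficient and 2 wild type preparations, 1 of each on the 430A array and 1 of each on the larger MOE430_2 array. Ratios are Icsbp-deficient over wild type on the log2 scale, and ± is the moderated standard error over n = 2 array types. It is borrowed mostly from other genes, so it does not measure how far the array types differ for a gene.

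The targeted gene was still read by both of its probe sets on the Icsbp-deficient arrays. For the first probe set the scaled signal was 3059 in wild type and 2776 in Icsbp-deficient GMP on the 430A array, and 4798 and 2725 on the MOE430_2 array. Its mean log2 ratio was -0.48 ± 0.16, with a limma adjusted p of 0.124 over all probe sets. For the second probe set the scaled signals were 3074 and 3234 on the 430A array and 1847 and 1892 on the MOE430_2 array, a mean log2 ratio of 0.06 ± 0.12 with an adjusted p of 0.832. The part of the gene that was deleted is not given in the sources used here, so these probe sets neither bear out nor contradict the labels. Of 7 tested members of the IRF family, Irf5 fell by 0.86 ± 0.18 (adjusted p = 0.0157) and Irf1 rose by 0.55 ± 0.13 (adjusted p = 0.0318), and adjusted over the list alone 2 rose and 2 fell, Irf2 (0.68 on the 430A and 0.29 on the MOE430_2 arrays) and Irf8 being the others. The family's median log2 ratio was 0.01 and its mean -0.04, and camera placed it lower with an adjusted p of 0.989.

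Icsbp-deficient GMP had lower transcripts of basophil, mast cell and eosinophil genes, with 8 of 8 tested members lower. Transcripts of the list of secondary and tertiary granule and related neutrophil genes were higher, in 11 of 19 cases. The deepest fall was in Ly86, a surface protein that pairs with the Toll-like receptor relative Cd180, which was 27.7-fold lower at a log2 ratio of -4.79 ± 0.17 (limma adjusted p = 1.95e-07). Its signal in Icsbp-deficient GMP lay close to the offset, so this fold is understated. Klf4, a transcription factor of monocyte differentiation, was 6.70-fold lower at -2.74 ± 0.25, and the mast cell protease Cpa3 was 7.0-fold lower at -2.81 ± 0.15. Among called genes that changed at least 2-fold on both array types, the largest rises were in Cd177 and Chil3. Cd177, a neutrophil surface glycoprotein, was 7.85-fold higher at 2.97 ± 0.18. Chil3, a chitinase-like secreted protein, was 6.83-fold higher at 2.77 ± 0.13.

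In all, 579 of 7820 genes passed the test, of which 322 rose and 257 fell. All 579 had the same sign on both array types, which a call required, since ratios of opposite sign could not pass at this threshold. At an unadjusted p under 0.05 the count was 1665. At least a 2-fold change on both array types was seen for 44 of the genes that rose and 45 of those that fell. Over probe sets, 406 rose and 290 fell of 13576 tested. Of 227 called genes with more than 1 tested probe set, 10 had another probe set of opposite sign, and 0 had one called in the opposite direction. The calls rest on array type as a block, since without it the only gene called was Ly86, and leaving out any single array in that unblocked model gave between 22 and 71 genes. Without the intensity trend in the variance 330 genes passed, and without the filter on low signals 287 did.

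**Figure D1:**
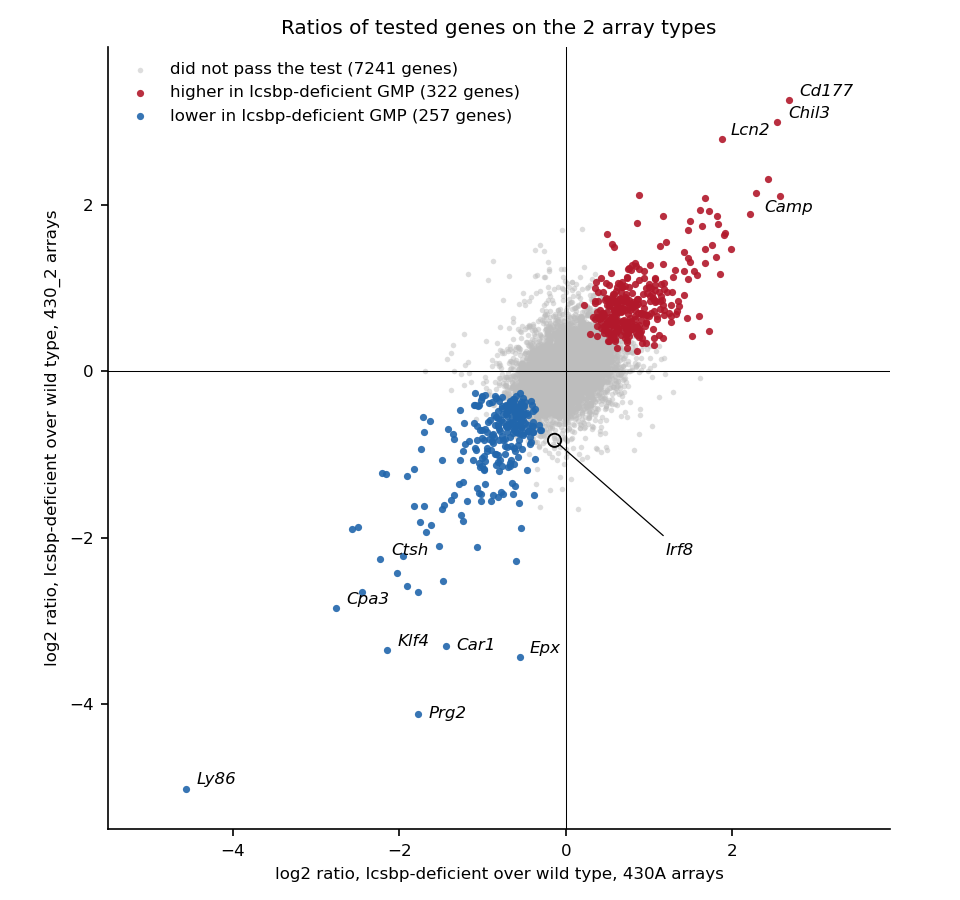
Log2 ratio of Icsbp-deficient over wild type GMP for each tested gene on the 430A arrays (x axis) and on the MOE430_2 arrays (y axis), with 322 genes that rose in red, 257 that fell in blue and the rest in grey. Ly86 lies apart at the lower left, at -4.57 and -5.01, and Cd177 at the upper right, at 2.68 and 3.26.

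The list of secondary and tertiary granules, the neutrophil storage organelles formed after the primary granules, rose as a group. It also holds neutrophil genes whose products are not granule contents, among them the cytosolic S100a9 and the receptor Cxcr2. Of 19 measured members 11 rose and 0 fell, and adjusted over the list alone 13 rose and 1 fell, the fall being the peptidoglycan-binding Pglyrp1 at -0.58 ± 0.17 (-0.93 on the 430A and -0.23 on the MOE430_2 arrays). Besides Cd177 and Chil3 the rises included the siderophore-binding protein Lcn2 at 2.34 ± 0.19 (5.06-fold), the cathelicidin Camp at 2.22 ± 0.14 (4.64-fold), the collagenase Mmp8 at 1.88 ± 0.17 and the calcium-binding S100a9 at 1.57 ± 0.10. Ngp at 1.5 ± 0.23 and lactoferrin, Ltf, at 1.08 ± 0.24 rose as well, at 2.12 and 1.65 on the MOE430_2 and 0.88 and 0.50 on the 430A arrays. The list's median log2 ratio was 0.96 (camera adjusted p = 3.37e-14, and adjusted p = 0.52 with an estimated correlation), above 100% of random lists on each array type. The form with an estimated correlation rests on 1 residual degree of freedom and called 0 lists. Its adjusted p, here and below, therefore cannot decide whether a list moved. The preset form treats the genes of a list as nearly independent, so its p is too small where they vary together. The estimated correlation was 0.181 for this list, 0.143 for eosinophil, basophil and mast cell genes and 1 for erythroid genes. It lay between -0.2 and 0.0877 for the other lists, and these estimates also rest on 1 residual degree of freedom. Without the filter on low signals the granule list's median was 0.607 (camera adjusted p = 1.18e-12). Members of this list that did not pass included Cxcr2 at 0.27 ± 0.24 (adjusted p = 0.574; -0.13 on the 430A and 0.66 on the MOE430_2 arrays), Mmp9 at 0.29 ± 0.22 (adjusted p = 0.498) and Padi4 at -0.28 ± 0.24 (adjusted p = 0.559; -0.63 and 0.07).

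Of 11 measured primary granule genes, which mark GMP themselves, 3 rose and 0 fell, and adjusted over the list alone 3 rose and 1 fell, Nkg7 being the fall at -0.29. The risers were Lyz2 at 1.15 ± 0.11, Lyz1 at 0.84 ± 0.10 and the protease inhibitor Serpinb1a at 0.55 ± 0.11. Lyz1 and Lyz2 are near-identical lysozyme genes whose probe sets can share targets, and another Lyz1 probe set gave 2.36. The major azurophil proteins had ratios near 0, with Mpo at -0.02 ± 0.08, Elane at 0.05 ± 0.09, Prtn3 at -0.02 ± 0.08 and Ctsg at 0.01 ± 0.08. These 4 ranked among the 47 highest probe sets on each array, where signal can saturate. The list had a median log2 ratio of 0.09 (camera adjusted p = 0.0142, and adjusted p = 0.52 with an estimated correlation), and its call ended without the intensity trend, at an adjusted p of 0.0574. The median was 0.253 with scaling alone, 0.157 with cyclic loess, and 0.0548 on the 430A and 0.138 on the MOE430_2 arrays.

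**Figure D2:**
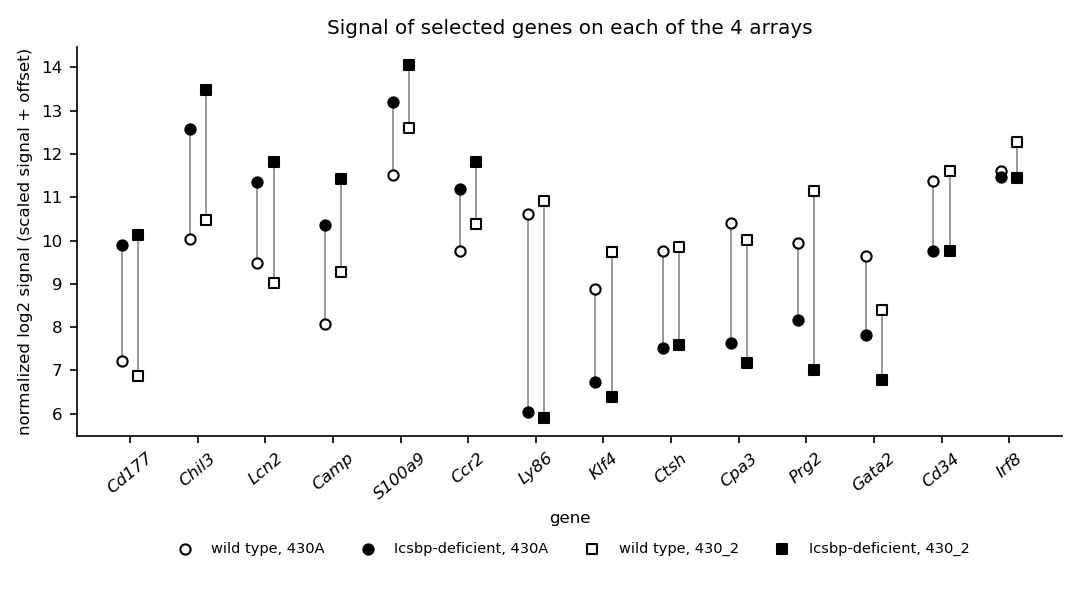
Normalized log2 signal (y axis) of genes the text names (x axis) on each of the 4 arrays, with open symbols for wild type, filled symbols for Icsbp-deficient GMP, circles for 430A and squares for MOE430_2 arrays, and a line joining the arrays of a type. Cd177 to Ccr2 lie higher and Ly86 to Cd34 lower in Icsbp-deficient GMP on both types, and Irf8 shows ratios of -0.13 and -0.83.

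Monocyte and macrophage genes split. Of 25 measured members 11 rose, 4 fell and 10 did not pass, and adjusted over the list alone 14 rose and 4 fell. The falls were Ly86, Klf4, the lysosomal protease Ctss at -1.12 ± 0.19 and Irf5. The rises included the chemokine receptor Ccr2 at 1.43 ± 0.12 (2.69-fold, adjusted p = 7.29e-05), the oxidase subunit Cybb at 1.17 ± 0.16, the lectin receptor Clec4a2 at 1.05 ± 0.14, the endosomal protein Cd68 at 1.03 ± 0.14 and the signalling adaptor Tyrobp at 0.94 ± 0.11. Csf1r, the receptor for macrophage colony-stimulating factor, had a ratio of -0.01 ± 0.11 (adjusted p = 0.956). The list's median was 0.62 and its mean 0.11 (camera adjusted p = 0.000823, and adjusted p = 0.52 with an estimated correlation), and its call ended with the values as deposited, at an adjusted p of 0.174. Without the filter on low signals the median was 0.142 (adjusted p = 0.00801), and on the array types alone it was 0.352 (430A) and 0.506 (MOE430_2).

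Subunits of the phagocyte oxidase, which makes superoxide, rose in 4 of 6 cases, and in 5 adjusted over the list alone. Beside Cybb these were Ncf1 at 0.56 ± 0.12, Cyba at 0.56 ± 0.11 and Ncf4 at 0.46 ± 0.12, with a list median of 0.51 (camera adjusted p = 0.000287, and adjusted p = 0.52 with an estimated correlation). Cyba is 1 of the 50 tested genes nearest to Irf8 on its chromosome. Cytokine and chemokine receptors rose in 6 of 29 cases and fell in 0, with 9 rises adjusted over the list alone. They were Ccr2, the tumour necrosis factor receptor Tnfrsf1b at 1.03 ± 0.14, the interferon gamma receptor Ifngr1 at 0.96 ± 0.12, Il17ra at 0.64 ± 0.13, and the granulocyte-macrophage colony-stimulating factor receptor chains Csf2rb and Csf2ra, both at 0.55. Csf2ra was at 0.74 on the 430A and 0.35 on the MOE430_2 arrays. The receptor list had a median of 0.29 (camera adjusted p = 2.18e-06, and adjusted p = 0.52 with an estimated correlation).

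Lysosomal genes moved both ways, with 7 of 29 rising and 2 falling, and 7 and 3 adjusted over the list alone. The falls were the cathepsin Ctsh, 4.73-fold lower at -2.24 ± 0.15, and Ctss. The rises included Gm2a at 0.72 ± 0.12, Neu1 at 0.64 ± 0.13, Ctsl at 0.55 ± 0.14, Man2b1 at 0.55 ± 0.10 and Ctsb at 0.54 ± 0.10, all enzymes or cofactors of lysosomal breakdown. The list median was 0.18 and camera gave an adjusted p of 0.0287, with adjusted p = 0.536 with an estimated correlation, 0.0574 without the intensity trend, 0.0614 without the block and 0.18 with the values as deposited, where the median was 0.0868. Of 19 pattern recognition genes, which sense microbes, the nucleic acid sensor Tlr7 rose by 1.59 ± 0.22 and Ly86 fell, the same 1 rise and 1 fall adjusted over the list alone, while Tlr6 at 0.58 and Tlr1 at 0.33 did not pass. This list had a positive median, 0.13, and a negative mean, -0.05, and camera, which placed it higher, gave an adjusted p of 0.274. Its median was 0.263 on the 430A and 0.066 on the MOE430_2 arrays.

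The genes of eosinophils, basophils and mast cells fell in 8 of 8 tested cases, also adjusted over the list alone. The list holds 25 genes, of which 19 were on shared probe sets and 8 passed the filter on low signals. Prg2, the eosinophil major basic protein, was 7.70-fold lower at -2.94 ± 0.39, the immunoglobulin E receptor chains Fcer1a and Ms4a2 fell by 1.99 ± 0.25 and 1.59 ± 0.24, and the eosinophil peroxidase Epx fell by 1.99 ± 0.47. Gata2, a transcription factor these lineages share with stem cells, fell by 1.72 ± 0.17, the histamine-forming enzyme Hdc by 1.00 ± 0.14 and the basophil protease Mcpt8 by 0.87 ± 0.15. The size differed between array types for Prg2, at -1.77 on 430A and -4.12 on MOE430_2, and for Epx, at -0.56 and -3.43. The list median was -1.86 (camera adjusted p = 1.62e-12, and adjusted p = 0.52 with an estimated correlation), below all random lists on both array types. Without the filter the median was -0.516 (adjusted p = 8.71e-06), and with the values as deposited it was -1.17.

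Stem and multipotent progenitor genes fell in 4 of 12 cases and rose in 0, with the same counts adjusted over the list alone. They were the surface protein Cd34 at -1.73 ± 0.13, the homeobox factor Hoxa9 at -1.47 ± 0.15 and the transcription factors Tal1 at -0.95 ± 0.16 and Sox4 at -0.77 ± 0.13, and the list median was -0.28 (camera adjusted p = 0.00112, and adjusted p = 0.52 with an estimated correlation). On the 430A arrays the median was -0.481, at percentile 0 of random lists, and on the MOE430_2 arrays -0.129, at percentile 9.33. With the 60th percentile filter it was -0.772. Among 9 genes of surface proteins used in or near such sorts, the Fc receptor Fcgr3 rose by 1.00 ± 0.11, the integrin Itgam by 0.76 ± 0.17 and Ptprc by 0.55 ± 0.15 (0.85 on the 430A and 0.25 on the MOE430_2 arrays), Cd34 and Ptprcap (-0.86 ± 0.16) fell, and Kit was at 0.28 ± 0.11 (adjusted p = 0.19). Adjusted over the list alone the counts were again 3 and 2, and camera gave the list an adjusted p of 0.408.

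Erythroid genes fell in 2 of 9 cases, the carbonic anhydrases Car1 at -2.37 ± 0.35 (-1.44 on the 430A and -3.30 on the MOE430_2 arrays) and Car2 at -2.21 ± 0.20, and in 3 adjusted over the list alone, the added gene being Klf1 at -0.97 ± 0.28 (-0.30 on the 430A and -1.63 on the MOE430_2 arrays). Ermap, at -0.73 ± 0.30 (-0.04 and -1.41), did not pass. The list median was -0.52 (camera adjusted p = 0.00142, and adjusted p = 0.61 with an estimated correlation). On the 430A arrays the median was -0.13, at percentile 17.9 of random lists, and on the MOE430_2 arrays -0.77, at percentile 0. It was -0.19 with the values as deposited and -0.328 with a floor. Of 10 megakaryocyte genes only the integrin Itga2b fell, by 0.86 ± 0.17, also over the list alone. Selp at -0.65 (-1.26 on the 430A and -0.03 on the MOE430_2 arrays), Gp1bb at 0.24 and Rap1b at 0.23 did not pass. That list had a median of 0.05 and a mean of -0.06, and camera, placing it higher, gave an adjusted p of 0.973.

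Among myeloid transcription factors 7 of 16 rose and 2 fell, and adjusted over the list alone 9 rose and 2 fell. The falls were Klf4 and Hoxa9. The rises included the CCAAT/enhancer-binding protein genes Cebpd at 1.12 ± 0.13, Cebpa at 0.69 ± 0.12 and Cebpb at 0.50 ± 0.13. The others were the immediate early gene Fos at 1.08 ± 0.17, the inhibitors of differentiation Id2 at 0.85 ± 0.20 and Id1 at 0.76 ± 0.15, and the clock gene Per3 at 0.64 ± 0.17. The median was 0.37 (camera adjusted p = 0.00371, and adjusted p = 0.52 with an estimated correlation), with an adjusted p of 0.0835 for the values as deposited. This was the only list whose movement in 1 direction passed under fry, at an adjusted p of 0.0176. Fry rests on 1 residual degree of freedom here, so this does not make the list firmer than others. The eosinophil, basophil and mast cell list, with 8 of 8 tested genes lower, had an unadjusted fry p of 0.0669.

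Genes of antigen presentation and dendritic cells fell in 4 of 13 cases and rose in 1, also adjusted over the list alone. The MHC class II genes H2-Aa (-1.44 ± 0.33), H2-Eb1 (-1.07 ± 0.25) and H2-DMa (-0.94 ± 0.14) and the invariant chain Cd74 (-1.07 ± 0.19) fell, and Id2 rose. The class II genes H2-Ab1, at 0.13 (adjusted p = 0.732), and H2-Oa, at -0.09 (adjusted p = 0.849), did not pass. H2-Aa was at -0.60 on the 430A and -2.28 on the MOE430_2 arrays, and H2-Eb1 at -0.56 and -1.58. The list median was -0.09 (camera adjusted p = 0.0411, and adjusted p = 0.52 with an estimated correlation), and its call ended in 5 other settings, with adjusted p from 0.0505 to 0.146. The median was -0.389 on the 430A and -0.145 on the MOE430_2 arrays, and -0.0245 with the values as deposited. Of 26 interferon-stimulated genes 4 rose and 0 fell, also over the list alone, namely Gbp2 at 1.32 ± 0.18, Ifit2 at 0.78 ± 0.15, Ifih1 at 0.55 ± 0.15 and Tap1 at 0.52 ± 0.14, and the list did not pass (camera adjusted p = 0.0629). Of 19 genes reported elsewhere as IRF8 targets, Cybb, Lyz2, Cd68 and the chemokine Ccl9 (0.65 ± 0.14, with 0.97 on the 430A and 0.34 on the MOE430_2 arrays) rose and Klf4 fell, with 4 rises and 2 falls adjusted over the list alone, Ctsc being added at -0.46 (-0.20 on the 430A and -0.73 on the MOE430_2 arrays). Camera gave that list an adjusted p of 0.105, and 0.00289 with the 60th percentile filter. Of 13 chemokines and cytokines, Il12a rose by 0.99 ± 0.15 and Ccl9 rose, Ccl6 fell by 1.09 ± 0.19, and Csf1, at -0.69, did not pass over all genes. Adjusted over the list alone 4 rose and 2 fell. This list's median was -0.01, its mean 0.03 and its camera direction up, with an adjusted p of 0.729. With the 60th percentile filter its median was 0.39 and the adjusted p 0.0447.

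**Figure D3:**
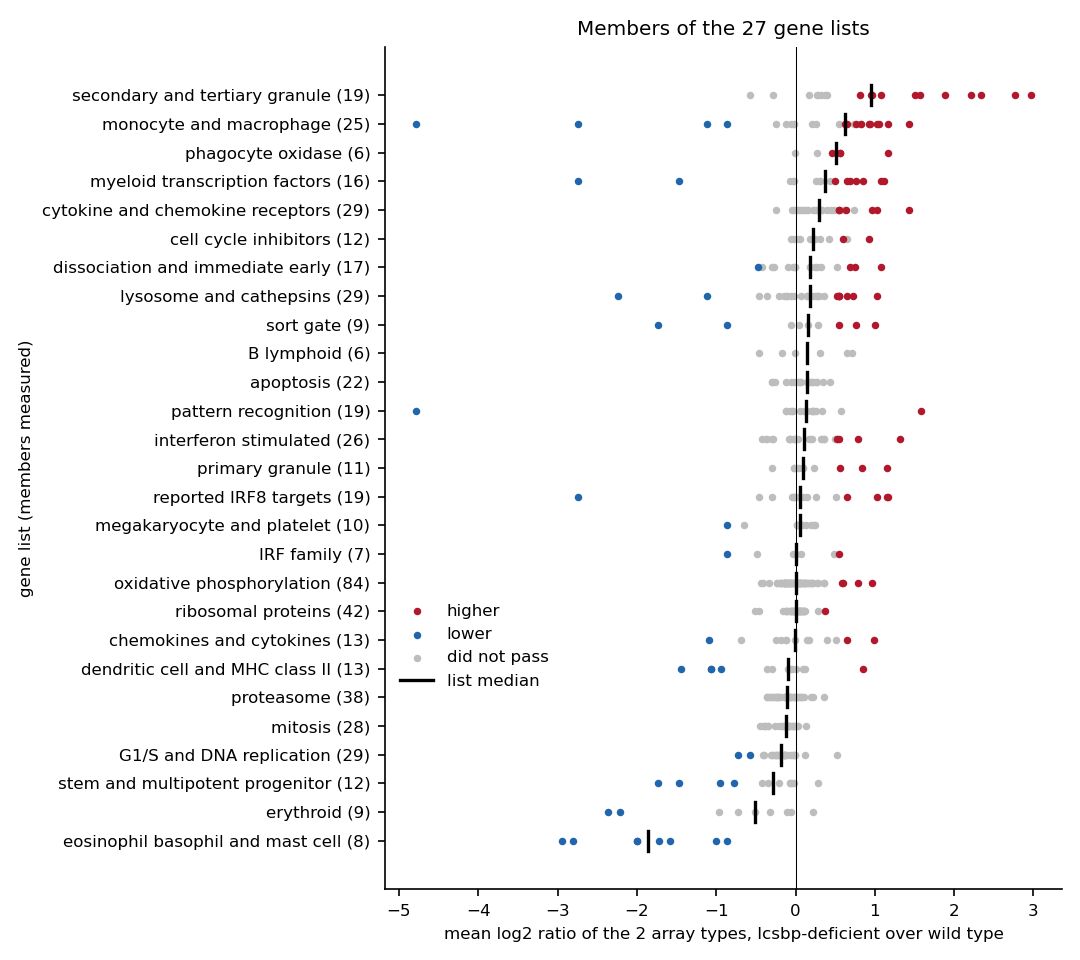
Mean log2 ratio of Icsbp-deficient over wild type GMP (x axis) for each member of the 27 gene lists tested (y axis, with the number measured), in red or blue where the gene rose or fell and in grey where it did not pass, with a black bar at each list's median. The secondary and tertiary granule list has the highest median, 0.96, and the eosinophil, basophil and mast cell list the lowest, -1.86.

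Cell cycle genes shifted slightly downward. Of 29 genes of G1/S and DNA replication, the cyclin Ccnd2 fell by 0.72 ± 0.12 and the replication licensing factor Cdc6 by 0.58 ± 0.15 (0.84 on the 430A and 0.32 on the MOE430_2 arrays), with 3 falls adjusted over the list alone, Cdk4 being the added one at -0.40. Pola1, at -0.41, and Cdk6, at 0.52, did not pass. The list median was -0.18 (camera adjusted p = 0.00142, and adjusted p = 0.52 with an estimated correlation). With the values as deposited the median was -0.205, at a camera adjusted p of 0.157. Of 28 mitosis genes 0 passed by limma either way, with Ncapg at -0.45, Kif23 at -0.41, Foxm1 at -0.39 and Cdk1 at -0.38. Kif23 was at -0.13 on the 430A and -0.70 on the MOE430_2 arrays, and Foxm1 at -0.19 and -0.59. The mitosis median was -0.12 (camera adjusted p = 0.0103, and adjusted p = 0.52 with an estimated correlation). With the values as deposited it was -0.175, at a camera adjusted p of 0.163. Of 12 cell cycle inhibitors the stress-induced Gadd45b rose by 0.93 ± 0.14 and the retinoblastoma gene Rb1 by 0.59 ± 0.14, and adjusted over the list alone 4 rose, adding Cdkn1a at 0.64 and Btg1 at 0.43 (median 0.22, camera adjusted p = 0.00371, and adjusted p = 0.52 with an estimated correlation). Proteasome subunits had 0 of 38 calls, also over the list alone, with Psmb8 and Psma7 at -0.36, Psmb9 at 0.36 and Psmd12 at -0.34. Their median was -0.11 (camera adjusted p = 0.0367, and adjusted p = 0.52 with an estimated correlation), and the call ended in 5 other settings, with adjusted p from 0.0577 to 0.669. The median was -0.055 on the 430A arrays and -0.19 with the values as deposited.

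Of 22 apoptosis genes 0 passed over all genes or over the list alone, the largest ratios being Xiap at 0.44, Birc3 at 0.35 and Casp8 and Bcl2 at -0.30, and camera gave an adjusted p of 0.274. Of 17 stress and immediate early genes, a check on handling during the sort, Fos, Klf6 (0.75 ± 0.19) and Nfkbia (0.69 ± 0.12) rose and the chaperone Hspa8 fell by 0.48 ± 0.10, with 3 rises and 2 falls over the list alone. Fosl2, at 0.52 (1.28 on the 430A and -0.24 on the MOE430_2 arrays), did not pass, and camera gave 0.310. Of 84 oxidative phosphorylation genes 4 rose and 0 fell, also over the list alone, Ndufs5 at 0.97 ± 0.13, Cox6b2 at 0.79 ± 0.17 (1.17 on the 430A and 0.40 on the MOE430_2 arrays), Cox7a2l at 0.60 ± 0.11 and Atp5e at 0.59 ± 0.12, with a camera adjusted p of 0.747. Of 42 ribosomal protein genes Rpl22 rose by 0.37 ± 0.09 and 0 passed over the list alone, with Rps27 at -0.51, Rpl12 at -0.47 and Rpl37 at 0.29. Their median was 0.0023 and their mean -0.0022, camera gave 0.805, and with scaling alone the median was 0.15 at an adjusted p of 0.00814 and with the values as deposited 0.032 at 0.0111.

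Lymphoid markers were mostly below the level tested. Of 6 B lymphoid genes 0 passed over all genes and 1 adjusted over the list alone, the surrogate light chain gene Igll1 at 0.71 ± 0.20, and Vpreb1 was at 0.64, Blk at -0.46 and Cd79b at 0.31 (camera adjusted p = 0.342). Of 3 tested T and NK cell genes, too few for the list test, the cytotoxic protease Gzmb fell by 2.24 ± 0.22, also over the list alone, with Zap70 at 0.31 and Klrk1 at -0.22. Granzyme B is also known as a product of mast cells.

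Outside the lists, the genes with the largest rises were the dynein-related Tctex1d1 at 2.37 ± 0.15, the sialic acid receptor Siglece at 2.35 ± 0.22, the zinc finger factor Plagl1 at 2.05 ± 0.17, the receptor transporter Rtp4 at 1.84 ± 0.21, the calcium channel subunit Cacna2d2 at 1.82 ± 0.22, the retinaldehyde reductase Dhrs3 at 1.80 ± 0.15, the actin-binding Cnn3 at 1.79 ± 0.13, Dmkn at 1.77 ± 0.13, the stress-activated kinase Mapk13 at 1.77 ± 0.22 and Mocos at 1.73 ± 0.22. The largest falls outside the lists were Gm6958 at -2.55 ± 0.21, the growth factor receptor adaptor Grb10 at -2.23 ± 0.18, the small GTPase Rab38 at -2.23 ± 0.17, the protease inhibitor Ctla2a at -2.18 ± 0.23, the Ras inhibitor Rasa4 at -2.09 ± 0.21 and Bex1 at -1.81 ± 0.19. All of these had adjusted p at or below 0.000965. The ranking covers called genes that changed at least 2-fold on both array types. Probe sets carried only by the MOE430_2 array are not in it.

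The array types ranked the changes alike in part. Across 13576 probe sets, which are not independent replicates, the log2 ratios of the array types correlated with a Pearson r of 0.491 and a Spearman rho of 0.380, and 62.8% had the same sign. At least 2-fold rises numbered 176 on the 430A and 207 on the MOE430_2 arrays, with 64 on both against 2.68 for independent lists. At least 2-fold falls numbered 151 and 152, with 68 on both against 1.69 for independent lists. Of the probe sets with 2-fold changes on both types, 1 went in opposite directions.

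The MOE430_2 array carries 22411 further probe sets, which were compared between 1 array per genotype without a test. Of 6084 above the level filter, 108 were at least 2-fold higher and 95 at least 2-fold lower in Icsbp-deficient GMP. These counts depend on the offset, with 252 higher and 214 lower at an offset of 16, and 47 and 24 at an offset of 100. The named genes with the largest differences upward were Tmem178 at 4.44 on the log2 scale (21.7-fold), E330020D12Rik at 2.26, Cd300lb at 2.22, Ptgfrn at 2.02 and Slc36a2 at 1.99. Those with the largest differences downward were the lymphoid factor Ikzf2 at -2.15, another Ms4a2 probe set at -2.14, Aff3 at -1.91, the angiopoietin Angpt1 at -1.81 and another Ctsh probe set at -1.79.

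Actin and Gapdh control probe sets gave similar 3' to 5' ratios for the genotypes of a type, and those of 18S ribosomal RNA differed. The actin 3' to 5' signal ratio was 1.03 in Icsbp-deficient and 1.00 in wild type GMP on the 430A arrays, and 1.44 and 1.47 on the MOE430_2 arrays, and the Gapdh ratio lay between 0.765 and 0.818 on all 4. The 18S signal on the 430A arrays was 119% of the trimmed mean at the 5' and 435% at the 3' end in Icsbp-deficient GMP, against 1240% and 687% in wild type, and on the MOE430_2 arrays 87.4% and 40.3% against 14.0% and 27.2%. The 3 Xist probe sets gave log2 ratios of -0.62, -0.14 and -0.03 on the 430A and 2.14, 0.81 and 0.18 on the MOE430_2 arrays, and the Y-linked gene Eif2s3y gave 0.84 and 0.07. None of the 4 tested sex-linked genes passed, the mean ratios being 0.46 for Eif2s3y, 0.25 for Kdm5d, 0.21 for Uty and 0.07 for the brightest Xist probe set.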

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

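One value stood out in data outside the gene comparisons. No test was run on it and no explanation was weighed. The control probe set for the 5' end of 18S ribosomal RNA reached 87.4% of the trimmed mean signal on the Icsbp-deficient MOE430_2 array, against 14.0% on the wild type array of that type. On the 430A arrays the order was opposite, with 119% in Icsbp-deficient and 1240% in wild type GMP. The measure tells of ribosomal RNA in the labelled material of each array and was not used in any ratio.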

How the results depend on the processing

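All alternatives had been chosen beforehand. The count of 579 genes (696 probe sets) lay between 452 and 832 genes (507 and 865 probe sets) with other normalizations, offsets, a floor, the 60th percentile filter, robust variances or mean probe sets, and those settings shared between 447 and 579 genes with it. It was 287 (266 probe sets) with no filter, where more genes are tested, 330 (267) without the intensity trend, and 1 (2) with no replicate block, where the difference between array types enters the error. With the values as deposited limma called 0 genes and 0 probe sets, with 14 genes at an unadjusted p under 0.05: the unscaled 430A arrays put the ratios of the array types apart and shift the median of all ratios by -0.65, so ratios in that setting are given relative to it. Each array left out in turn from the unblocked model gave 22 to 71 genes and 17 to 85 probe sets, the lone array being assumed to vary like the other genotype. Other thresholds gave 223 probe sets (also 2-fold), 1081 (adjusted p under 0.1) and 132 (2-fold on both array types, untested). Of the 101 named genes that passed, all 101 kept their direction on each array type alone, which the test itself required. The exception among unblocked fits was Irf1, at -0.019 to 1.12 with arrays or array types left out. Calls were also lost among the 101. Without the intensity trend 30 no longer passed, without the filter 27, with mean probe sets 15, with the values as deposited 98 and with no replicate block 100. Among genes named by the fixed rule that did not pass, leaving out arrays or array types gave ratios of both signs for Gp1bb (-0.021 to 0.54), Fosl2 (-0.24 to 1.28), Psmb9 (-0.036 to 0.76), Xist (-0.72 to 0.86), Zap70 (-0.31 to 0.91), the second Irf8 probe set (-0.40 to 0.53), Birc3 (-0.12 to 0.81), Foxm1 (-0.99 to 0.24), Rps27 (-1.05 to 0.068), Eif2s3y (-0.42 to 1.41), Kdm5d (-0.30 to 0.85), Uty (-0.11 to 0.52), Klrk1 (-0.50 to 0.019) and Cdk6 (-0.47 to 1.44), and the values as deposited gave -0.065 for Xist and -0.068 for that Irf8 probe set. The number of lists called, 15, was 10 to 15 in other fits, 0 with an estimated correlation (lowest unadjusted p 0.108) and 1 with fry. The last 2 rest on 1 residual degree of freedom, so they had little power and cannot decide on the other calls. Those calls in turn rest on the preset correlation, which treats the genes of a list as nearly independent. Lists that did not pass changed sign as follows: IRF family -0.0058 with scaling alone and -0.013 as deposited, chemokines and cytokines 0.17 as deposited, 0.39 with the 60th percentile filter (adjusted p = 0.0447, so called there) and 0.118 without replicate 1 (-0.0476 without replicate 2), oxidative phosphorylation -0.075 as deposited and -0.0326 without replicate 1 (0.0337 without replicate 2), ribosomal proteins -0.00288 without a filter, -0.00589 with mean probe sets, -0.00135 without replicate 2 and -0.0115 without replicate 1. The correlation of the array types, 0.491, was 0.403 as deposited, 0.360 without a filter and 0.554 with the 60th percentile filter. The 203 probe sets that differed 2-fold on the MOE430_2 array alone became 466 with an offset of 16 and 71 with an offset of 100, since the offset sets how far low signals can differ. Other causes were not tested, and low signal over background limits the genes near the filter.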

Other observations

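Except for the test of the 50 genes nearest to Irf8, the tests in this part were chosen after the results they bear on had been seen, and so were the genes of the next 3 sentences. Cd24a, a surface glycoprotein of immature blood cells, fell on all 3 of its tested probe sets, by 1.51 to 1.61 on the log2 scale with limma adjusted p from 9.68e-05 to 0.000274. Immunoglobulin alpha heavy chain transcripts, Igha, a plasma cell product, fell on 3 probe sets by 1.37 to 1.68. Asns, the asparagine synthetase of the amino acid stress response, fell by 1.49 and 1.69 on 2 probe sets, and the chromatin protein Hmgn1 fell by 0.79 to 1.06 on 3.

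Neutrophil granule genes rose while the basophil, mast cell and eosinophil genes fell. Dilution by cells without primary granule transcripts is argued against by the primary granule genes, whose median log2 ratio was 0.0915. The median was 0.23 for the 7 besides the very bright Mpo, Elane, Prtn3 and Ctsg, whose signal can saturate and so hide a fall. The 8 lower genes ranged from -2.94 to -0.87. Diluting cells that carry primary granule transcripts themselves are not covered. This includes cells that carry Lyz2, Lyz1 or Serpinb1a, which are among the 7 and rose. Mature neutrophils carried through the sort remain open: they would bring late transcripts too, and 9 late markers outside the granule list had a median log2 ratio of 0.315 (SD 0.395, 1 called, Slpi) against 0.955 (SD 1.02) for all 19 tested members of that list, with a two-sided permutation p of 0.054. Granule-stage precursors that had lost Kit also remain open, since Kit, with a log2 ratio of 0.277, could itself be regulated. Fewer cells committed to the basophil, mast cell and eosinophil lineages inside the gate, or less transcript in each such cell, is a biological hypothesis. With 8 of 8 tested genes lower on both array types, bulk arrays cannot separate these alternatives. Falls were not confined to these lineages. Stem and multipotent progenitor genes fell in 4 of 12 cases and erythroid genes in 2 of 9, with 0 rises in either list.

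Irf8 probe sets kept most of their signal on the arrays labelled Icsbp-deficient. Exchanged labels within 1 array type would turn the ratios of that type around, but the ratios of the array types correlated at 0.4906 across probe sets, which argues against an exchange in 1 type and not against one in both. Transcripts of the altered allele that the probe sets still read may account for the signal. The lower of the probe sets had a log2 ratio of -0.4811, and without the position of the deletion this stays open.

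Genes that differed were more frequent around Irf8 than elsewhere. Of the 50 tested genes nearest to Irf8 on its chromosome, 8 were called (16.0%), against 7.35% of all others, an odds ratio of 2.40 (95% interval 0.969 to 5.21, two-sided Fisher exact p = 0.0291). With the nearest 20 genes the ratio was 4.19 (5 called, interval 1.19 to 12.2, Fisher exact p = 0.0133) and with the nearest 100 it was 1.40 (10 called, interval 0.644 to 2.71, Fisher exact p = 0.332), and of 7810 genes taken as centres 2.06%, 4.46% and 25.3% had as many called genes among their nearest 20, 50 and 100. A candidate explanation is a chromosome segment of the other parental strain carried along with the mutation, since the wild type 430A label names a mixed background, though the intervals for 50 and 100 genes include 1, that for 20 genes does not, and local co-regulation was not tested. The 8 genes are Usp10 (-0.75), Klhdc4 (-0.61), Slc7a5 (-0.52), Zfpm1 (-1.16), Abcb10 (-1.28), Gcsh (-0.52), Cyba (0.56) and Rhou (1.27).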
